A study of Mus musculus with 4 samples.

How the data were processed

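Kidney RNA from wild-type mice and from mice labelled Tet2 knockout was profiled after sham surgery or after ischemia of the kidney for 60 min and reperfusion for 24 h, per the labels' protocols. The labels name male C57Bl/6 mice in all 4 groups. Each group was measured on 1 array with RNA pooled from 3 mice. The mice of a pool cannot be separated, so no spread between mice could be computed, and the number of arrays limits the precision of every value. Per the labels' protocols, RNA was extracted with Trizol and biotin-labelled for Affymetrix expression arrays.

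The deposited values are log2 signals of 45037 probe sets in 4 columns, 1 column per array, and all 4 columns were used. That the unit is log2 was read from the values, which lie between 2.51 and 14.97, with column medians of 6.33 for wild-type sham, 6.28 for wild-type ischemia-reperfusion, 6.30 for knockout-labelled sham and 6.31 for knockout-labelled ischemia-reperfusion. The submitters' processing notes name MAS5, an Affymetrix program that turns probe intensities into 1 signal per probe set, and give no version, scaling target or filter. The columns' percentiles lie close together without being identical: at matching ranks a column differed from the mean of the 4 columns by at most 0.10 on the log2 scale and by 0.016 on average. The values are not centred per probe set. The authors' method of scaling stays unknown, and so does the part MAS5 played, because the log2 ratio between the sham arrays had its smallest SD, 0.18, in the lowest of 10 equal bins of signal.

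Probe sets were matched to genes through the annotation of the array. Exactly 1 gene symbol was listed for 34945 probe sets, several symbols for 932, and 9160 were not listed in that annotation; the values contain 0 control probe sets of the AFFX type. The symbols were compared with a RefSeq gene table of mouse assembly GRCm38.p6 through Entrez gene identifiers, which were found there for 34741 probe sets, and 0 symbols needed an update. That table also gave the order of neighbouring genes. Each of the 18193 genes was read from 1 probe set, the one with the highest mean log2 signal over the arrays. A probe set with the suffix _x_at, which marks probes that can bind other transcripts, was used only for the 100 genes that had no other.

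Signals below a floor were set to the floor. The floor was the 40th percentile of all signals pooled over the arrays, a log2 signal of 5.72 or a linear signal of 52.8. In a comparison, a gene counted as measured if it was at or over the floor in 1 or more of the arrays compared, and 13808 genes reached the floor in 1 or more of the 4 arrays. Where a gene was at the floor on one side only, its fold is a lower bound and is written as at least N-fold.

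The 5 comparisons were log2 ratios: ischemia-reperfusion over sham within each genotype, knockout-labelled over wild type within each treatment, and the difference between the ischemia-reperfusion responses of the genotypes. With 1 array per group no test of these comparisons was made, and no p-value is given. A gene was counted as higher or lower at 2-fold or more. As a measure of technical error, the SD of log2 ratios between probe sets of the same gene, both at or over the floor, was 0.24 for ischemia-reperfusion in wild type, 0.41 for ischemia-reperfusion in the knockout-labelled pair, 0.20 for the sham arrays, 0.34 for the ischemia-reperfusion arrays and 0.39 for the difference of responses. That SD does not cover differences between mice. Pearson and Spearman correlations were computed across genes, which are not independent replicates.

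Before the data were examined, 29 gene lists with 620 members in all were fixed: tubular injury, proximal tubule, loop of Henle and distal tubule, collecting duct, podocyte, endothelium, fibroblast with mural cell and matrix, neutrophil, monocyte with macrophage and dendritic cell, lymphocyte, cytokine with chemokine and adhesion, interferon response, cell cycle, apoptosis and other cell death, p53 targets, oxidative stress defence, hypoxia and glycolysis, heat shock and unfolded protein, fatty acid oxidation and peroxisome, mitochondrial respiratory chain, immediate early genes, DNA methylation machinery, complement and coagulation, red blood cell, adrenal gland, adipose tissue, urothelium, skeletal muscle and reference genes. Of their members 562 were matched to a gene read on the array, 5 of them through an older symbol. The rest had no probe set listed under that symbol alone. For each list the median log2 ratio of the measured members was placed as a percentile among 10000 random lists of the same size matched on mean signal in 20 bins. The percentile describes these arrays and is no test between groups of mice. Some members are not specific: Enpep and Mme of the podocyte list and Pck1, Lpl and Fabp4 of the adipose list are also expressed by other kidney cells, and Pvalb stands on the distal tubule list and on the skeletal muscle list.

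Genes were named by a rule fixed before the data were examined. For each comparison it takes the 8 genes with the highest and the 8 with the lowest log2 ratio among those at or over the floor in every array compared, provided that no other probe set of the gene went the other way by 1.5-fold or more. It adds up to 4 genes per direction with the largest bounds, up to 4 members of each list with the largest log2 ratio in size, the Tet genes, and Havcr1, Lcn2, Slc34a1, Lrp2, Il6, Tnf, Ccl2 and Bcl2. Any other gene that is named was chosen after its values were seen, and this is said where it is named.

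The procedure was tested on simulated data for the wild-type comparison of ischemia-reperfusion with sham alone, with changed genes well over the floor. The noise was normally distributed with the robust SD of the ratio between the sham arrays, which leaves out their largest differences. The other comparisons, with larger technical SDs except for the sham arrays, were not simulated. With true log2 changes of 1.5 and 3 in either direction, 50 of 50 genes passed 2-fold in each of the 4 sets. Among unchanged genes 0 of 13212 passed, and 7.0% of 200 unchanged lists lay outside the central 95% of random lists. This cannot tell how many genes pass 2-fold falsely in the deposited arrays. The sham arrays themselves had 139 of 13474 measured genes at 2-fold. The alternatives tried, one at a time, were quantile normalization, a common median over detected probe sets, floors at the 20th and 60th percentile, a pseudocount in place of the floor, detection in every array compared, the median over a gene's probe sets, plain _at probe sets alone, thresholds of 1.5-fold and 3-fold, and a threshold of 3 robust SDs of the ratio between the sham arrays. Probe sets with several symbols or none were left out of the comparisons and counted separately. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.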

Results

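Gene expression was measured in whole kidneys of wild-type mice and of mice labelled Tet2 knockout, after sham surgery or after 60 min of ischemia and 24 h of reperfusion, an injury that damages mainly the tubules. Tet2 encodes an enzyme that oxidises methylated cytosine in DNA. There were 4 groups with 1 array each, and each array held RNA pooled from 3 mice. The arrays had 45037 probe sets, of which 60.4% were at or over the floor in wild-type sham, 59.8% in wild-type ischemia-reperfusion, 60.1% in knockout-labelled sham and 59.7% in knockout-labelled ischemia-reperfusion. Across all probe sets the sham arrays of the genotypes correlated most closely, with r = 0.993, and the knockout-labelled ischemia-reperfusion array stood farthest from its own sham array, with r = 0.963. No difference given here has a replicate check.

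Tet2 itself was not lower in the sham array labelled knockout. One of its probe sets had log2 signals of 9.96 in wild-type sham, 9.16 in wild-type ischemia-reperfusion, 9.87 in knockout-labelled sham and 8.74 in knockout-labelled ischemia-reperfusion. Its other probe set had 9.84, 9.30, 10.25 and 8.60 in the same order. Between the sham arrays the log2 ratios of knockout-labelled to wild type were -0.09 and 0.41, and between the ischemia-reperfusion arrays they were -0.41 and -0.70. A probe set outside the deleted part of a gene checks nothing, and the place of these probe sets relative to the deletion was not known here. For this reason the groups are called knockout-labelled throughout. Tet3 had log2 signals of 6.24, 6.14, 6.19 and 6.05 in the 4 arrays, and the highest Tet1 probe set lay near the floor with 5.77, 5.62, 5.78 and 5.82.

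**Figure D1:**
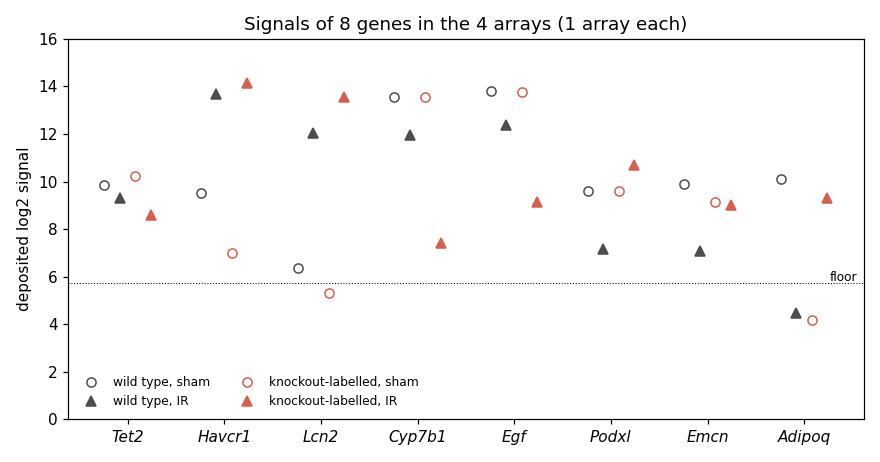
Log2 signal of Tet2, Havcr1, Lcn2, Cyp7b1, Egf, Podxl, Emcn and Adipoq in each of the 4 arrays, 1 point per array, with the floor of 5.72 as a dotted line. Tet2 has 9.84 in wild-type sham and 10.25 in knockout-labelled sham, and the fat gene Adipoq has 10.11 in wild-type sham, 4.46 in wild-type ischemia-reperfusion, 4.19 in knockout-labelled sham and 9.31 in knockout-labelled ischemia-reperfusion.

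The comparison of ischemia-reperfusion with sham in wild type asks which kidney genes differ 1 day after the injury. Genes of injured tubules were far higher after ischemia-reperfusion: the keratin Krt20 was 77.3-fold higher, Lcn2, an iron-carrier-binding protein used as a marker of kidney injury, 50.9-fold, and Havcr1, the tubular injury receptor KIM-1, 17.9-fold. Cyp4a14, a fatty acid hydroxylase, was 54.7-fold higher, the mitochondrial arginase Arg2 12.0-fold, the apolipoprotein Apoa4 10.3-fold, Anxa3 10.03-fold and the fibrinogen chain Fgg 8.44-fold. Among genes at the floor after sham, Fgb was at least 8.03-fold higher, the cytokine gene Clcf1 at least 6.46-fold, the macrophage gene Cd68 at least 4.94-fold and Mlkl, which encodes the effector of necroptosis, at least 4.68-fold. Lower after ischemia-reperfusion were Car3, a carbonic anhydrase, by 30.6-fold, Ifi27l2a by 12.7-fold, the integrin Itga8 by 9.66-fold, the fatty-acid-binding protein Fabp4 by 9.65-fold, the endothelial sialomucin Emcn by 7.10-fold, Rnase4 by 6.14-fold, Pdgfra by 5.81-fold and the kinesin Kif20b by 5.76-fold. The other probe set of Pdgfra had a log2 ratio of only -0.47, and that of Car3 -2.62.

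Of 13531 genes measured in the wild-type pair, 279 were higher and 295 lower at 2-fold or more. The tubular injury list had 15 of 23 measured members higher and 0 lower, with a median log2 ratio of 1.77, above all 10000 matched random lists. Cell cycle genes had a median of 0.62, also above all random lists, with 7 of 18 higher, among them the replication helicase genes Mcm6 at 6.26-fold, Mcm3 at 3.39-fold and Mcm5 at a bound of 3.26-fold, and Rrm2 at 3.38-fold; with a pseudocount in place of the floor that median was 0.28. Oxidative stress defence had 8 of 21 members higher and a median of 0.47, led by the glutathione transferase Gsta2 at 6.96-fold, Srxn1 at 4.73-fold, with other probe sets from 0.41 to 1.80 in log2 ratio, the metallothionein Mt2 at 3.58-fold and Nqo1 at 3.13-fold. With plain _at probe sets alone the median of that list was 0.031. In fatty acid oxidation 4 of 23 members were higher and 0 lower, with a median of 0.32; besides Cyp4a14, the thiolase Acaa1b was 2.54-fold higher, Slc25a20 2.16-fold and Cpt2 2.03-fold.

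Inflammatory genes were higher in part. The cytokine, chemokine and adhesion list had 6 of 26 members higher and 0 lower, with a median of 0.14 at percentile 99.6, or 0.031 with a pseudocount in place of the floor, and Cxcl1 was 4.92-fold higher, Icam1 2.78-fold and Cxcl10 2.75-fold. Csf1 was 2.37-fold higher, but its other probe sets had log2 ratios of 0.30 and 0.35. Il6 and Ccl2 were below the floor in both arrays, and Tnf differed by 1.01-fold. Apoptosis and other cell death had 2 of 28 members higher and 0 lower, with a median of 0.11 at percentile 92.1; besides Mlkl, Acsl4 was 3.26-fold higher, Casp8 1.85-fold and Bak1 1.74-fold, and Bcl2 was 1.11-fold lower. Among p53 targets the cell cycle inhibitor Cdkn1a was 4.001-fold and Aen 2.41-fold higher, the latter with log2 ratios of 0.44 and 0.86 on other probe sets, while the list's median was 0.13 at percentile 80.6. The immediate early list had a median of -0.09, with Myc 4.50-fold, Ccn1 4.10-fold and Maff 3.10-fold higher and Dusp1 4.70-fold lower. Complement and coagulation had 4 members higher and 2 lower of 16, with a median of 0.05; the fibrinogen chain Fga was higher, with a log2 ratio of 2.81, and the complement inhibitor Serping1 5.25-fold lower.

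Markers of the differentiated nephron were lower. The proximal tubule list had 8 of 38 members lower and 0 higher, with a median of -0.50, below all random lists; the amino acid transporter Slc7a13 was 3.96-fold lower, the oxysterol hydroxylase Cyp7b1 3.07-fold, the phosphate transporter Slc34a3 3.05-fold and the creatine synthesis enzyme Gatm 2.55-fold. Slc34a1, the main phosphate transporter of the proximal tubule, was 1.81-fold lower and the endocytic receptor Lrp2 1.67-fold lower. In the loop of Henle and distal tubule list 3 of 17 members were lower, with a median of -0.39; Pvalb was 2.91-fold lower, Egf 2.75-fold, Ptger3 2.28-fold and Cldn10 1.96-fold. The collecting duct list had a median of -0.17, and its members at 2-fold were Aqp4, 3.54-fold lower, and Elf5, 3.36-fold lower, whose other probe set had a log2 ratio of only -0.04.

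Genes of glomeruli, vessels and stroma were lower too, in an array that also held less fat and urothelial RNA than its sham control. Podocyte genes had a median of -0.98, below all random lists, with 6 of 12 lower: Tcf21 by at least 6.55-fold, Podxl by 5.42-fold, Ptpro by 5.02-fold and Cdkn1c by 4.05-fold. The other probe set of Podxl had a log2 ratio of -0.37. The podocyte gene Nphs1, named after its values were seen, differed little. Its log2 signals were 6.67 in wild-type sham and 6.36 in wild-type ischemia-reperfusion. Endothelial genes had a median of -0.86 with 6 of 15 lower, among them Tek by 3.99-fold, Ptprb by 3.33-fold and Plvap by 3.07-fold. The fibroblast, mural cell and matrix list had a median of -0.46 with 5 of 19 lower, among them Dcn by 4.26-fold and Tagln by 2.14-fold. Beside these, the adipose list had a median of -1.30 with 4 of 8 lower, the fat hormone gene Adipoq by at least 21.0-fold and Cidea by at least 15.5-fold, and the urothelium list a median of -0.59, with the uroplakin Upk3b 2.76-fold, Psca 2.66-fold and Upk3a 2.05-fold lower. Under the alternatives that kept the wild-type sham array, the smallest of these medians in size were -0.23 for fibroblast, -0.78 for adipose and -0.25 for urothelium genes. With the knockout-labelled sham array as control the adipose median was -0.32 and the urothelium median 0.38. That adipose median rests on the 4 members measured with this control, so it is not over the same genes. The podocyte and endothelium medians were then -1.01 and -0.95. The low urothelial signal of this array thus depended on the control. Cox8b, a cytochrome oxidase subunit of brown fat and muscle, was lower by at least 11.9-fold and Cck by at least 7.56-fold.

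**Figure D2:**
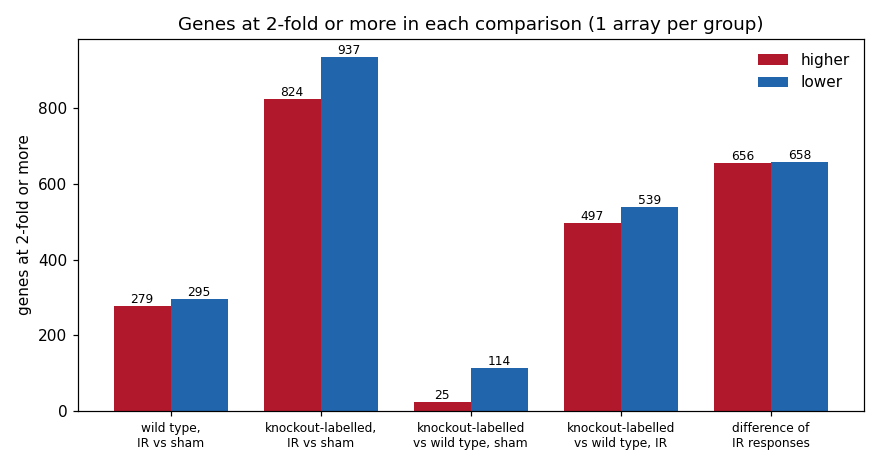
Bars show the number of genes higher and lower at 2-fold or more in each of the 5 comparisons, counted on an axis that starts at 0. The knockout-labelled pair has 824 higher and 937 lower after ischemia-reperfusion, against 279 and 295 in the wild-type pair, and the sham arrays have the smallest numbers, 25 and 114.

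The same comparison in the knockout-labelled pair asks how kidneys of the other genotype responded. The same injury genes led, at larger folds: Lcn2 was at least 230.2-fold higher, Krt20 at least 162-fold, Havcr1 139-fold, Fgb at least 58.5-fold and the small proline-rich protein gene Sprr2f at least 56.9-fold. The haemoglobin-binding protein haptoglobin, Hp, was 72.4-fold higher, Fgg 72.2-fold, the scaffold protein Akap12 47.5-fold, the calcium-binding protein S100a6 36.5-fold, Cyp27b1, the enzyme that makes active vitamin D, 30.1-fold, Fga 29.1-fold and Anxa3 24.6-fold. Proximal tubule genes led among those lower: Cyp7b1 was 70.7-fold lower, the brush border protease subunit Mep1b 57.8-fold, the organic anion transporters Slc22a19 45.6-fold and Slc22a7 24.96-fold, and Slc7a13 28.2-fold. Also lower were C1qtnf3 by 30.9-fold, the distal tubule growth factor Egf by 24.6-fold and Serpina1f by 20.1-fold. The largest bounds among lower genes were at least 11.8-fold for Gm32960, 9.88-fold for the chloride-bicarbonate exchanger Slc4a1, 9.47-fold for Methig1 and 8.06-fold for the apelin receptor Aplnr.

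In the knockout-labelled pair 824 of 13600 measured genes were higher and 937 lower at 2-fold or more. The tubular injury list had 22 of 23 members higher, with a median log2 ratio of 3.21. Immediate early genes had 14 of 21 higher and 0 lower, with a median of 1.62. With the wild-type sham array as control their median was 0.78, with 7 higher and 1 lower. Against the knockout-labelled sham array Maff was 7.88-fold higher, Klf6 7.35-fold and Fosl1 at least 6.07-fold. Fosl2 was 6.51-fold higher, although its other probe set had a log2 ratio of 0.29. The medians of 3.21 and 1.62 lay above all random lists. So did those of cell cycle genes, 0.50 with 6 of 19 higher, and of cytokine, chemokine and adhesion genes, 0.45 with 8 of 28 higher. With a pseudocount in place of the floor the cell cycle median was 0.099 and the cytokine median 0.13. Mcm6 was 5.70-fold higher, Mcm3 3.58-fold, Mcm4 2.82-fold and Mcm2 2.65-fold. Among cytokines Il34 was 6.55-fold higher, Cxcl2 at least 4.83-fold, the signalling inhibitor Socs3 4.40-fold and Cxcl1 4.49-fold, with log2 ratios of 0.76 and 3.50 on its other probe sets. Il6 was at least 1.11-fold higher and thus near the floor, Ccl2 was below it, and Tnf was 1.20-fold lower.

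Genes of p53 signalling and cell death were higher in part. The p53 list had a median of 0.73 at percentile 99.99, or 0.25 with the wild-type sham array as control. Cdkn1a was 18.2-fold, Btg2 3.08-fold and Aen 3.57-fold higher, with log2 ratios of 0.81 and 1.35 on the other probe sets of Aen. Apoptosis and other cell death had 7 of 29 members higher and 0 lower with a median of 0.10; Mlkl was at least 17.3-fold higher, Bak1 3.61-fold, Acsl4 3.61-fold and Bcl2l1, which encodes an inhibitor of apoptosis, 2.77-fold, while Bcl2 was 1.12-fold lower. Oxidative stress defence had 7 higher and 1 lower of 21, with a median of 0.13; Srxn1 was 10.5-fold higher, Mt2 7.65-fold, Mt1 6.17-fold and haem oxygenase Hmox1 4.74-fold. With plain _at probe sets alone that median was -0.27. The heat shock and unfolded protein list had a median of 0.37 at percentile 99.7. With the wild-type sham array as control its median was -0.07, with 3 members higher and 5 lower. Against its own sham array Hspb1 was 10.3-fold, Atf3 4.06-fold and Chac1 3.40-fold higher and Sdf2l1 3.21-fold lower. Complement and coagulation had 7 members higher and 2 lower of 16, with a median of 0.06 at percentile 66.1, or -0.13 over genes detected in both arrays, and besides the fibrinogen chains the plasminogen activator Plat was 5.41-fold higher, although its other probe set had a log2 ratio of 0.73.

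Proximal and distal tubule genes had lower medians than in the wild-type pair. The proximal tubule list had 23 of 38 members lower and 0 higher, with a median of -1.30; Hao2 was 9.23-fold and Slc22a30 7.48-fold lower. Slc34a1 was 2.32-fold lower and Lrp2 4.39-fold lower, with its other probe sets between -1.81 and -0.23 on the log2 scale. The loop of Henle and distal tubule list had 12 of 17 lower, with a median of -1.76; Pvalb was 11.1-fold lower, Cldn10 7.36-fold and the loop salt transporter Slc12a1 5.52-fold. Both medians lay below all random lists, while the collecting duct list, with the water channels Aqp4 9.37-fold and Aqp3 2.31-fold lower, had a median of -0.08. Fatty acid oxidation had a median of -0.07, with Pdk4 9.92-fold and Cyp4a14 8.71-fold higher and the dehydrogenase Acadm 2.98-fold lower.

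Some stromal and neutrophil genes were higher in an array that also held more fat and urothelial RNA than its sham control. The fibroblast, mural cell and matrix list had 7 members higher and 3 lower of 19, with a median of 0.11; the matrix protein Tnc was 9.01-fold higher, smooth muscle actin Acta2 5.25-fold, Postn 4.80-fold and Tagln 4.15-fold. The neutrophil list had 4 of 12 higher, with a median of 0.36 at percentile 99.9, or 0.059 over genes detected in both arrays; S100a8 was at least 19.8-fold and S100a9 14.4-fold higher. The podocyte list had a median of 0.41, with Cdkn1c 2.34-fold and Synpo 2.32-fold higher and Mme 4.18-fold and Tcf21 3.99-fold lower, or a median of 0.12 with the median over each gene's probe sets, and the endothelium list a median of -0.14. The adipose list had a median of 1.10 with 5 of 7 higher, Adipoq by at least 12.0-fold and Cidec by at least 6.22-fold, and over genes detected in both arrays a median of 0.16. Fabp4 was 6.28-fold higher, with other probe sets at log2 ratios of 0.11 and 2.31. The urothelium list had a median of 0.56, with Upk1b 2.29-fold and Krt5 1.97-fold higher.

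**Figure D3:**
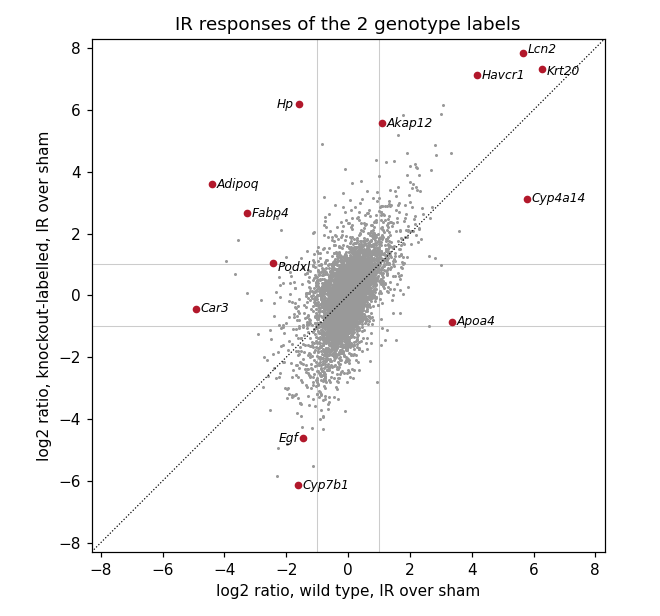
Log2 ratio of ischemia-reperfusion to sham in the knockout-labelled pair against that in the wild-type pair, 1 point for each of 13323 genes measured in both, with lines at 2-fold, a dotted diagonal, and genes at the floor in 1 array drawn at their bound. Havcr1, Lcn2 and Krt20 lie high in both pairs, Cyp7b1 and Egf lie low in both, and Hp, Fabp4 and Adipoq lie low in wild type and high in the knockout-labelled pair.

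The comparison of the sham arrays asks how kidneys of the knockout label differed without injury. Few genes were higher in the knockout-labelled sham array: the hydrolase gene Abhd1 was 17.8-fold higher, Azgp1 14.5-fold, the collagen Col5a2 7.99-fold, Etnppl 5.87-fold, Ptprn2 5.03-fold, Tmem87a 3.80-fold, Gsta2 3.63-fold and Ugt2b37 3.23-fold. Early response and injury genes were lower: the transcription factor Egr1 by 7.69-fold, S100a6 by 6.68-fold, the stress gene Nupr1 by 6.13-fold, Havcr1 by 5.72-fold, Ndrg4 by 4.89-fold, the keratin Krt18 by 4.54-fold and the chaperone Hspa1b by 4.10-fold. Elf5 was 4.90-fold lower, but its other probe set had a log2 ratio of -0.07, and that of Havcr1 had -1.37. At the floor on one side, Nat8f3 was at least 3.53-fold, Serpina1c 3.24-fold, BC023105 2.96-fold and C920006O11Rik 2.57-fold higher, the last with a log2 ratio of -0.05 on its other probe set, while Adipoq was at least 21.0-fold, Cidea 15.5-fold, Sptssb 13.2-fold and Cox8b 11.9-fold lower.

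Between the sham arrays 25 of 13474 measured genes were higher and 114 lower at 2-fold or more. Immediate early genes had a median log2 ratio of -0.71 with 8 of 20 lower and 0 higher, among them Fos by 2.97-fold, Btg2 by 2.72-fold and Junb by 2.36-fold; with a pseudocount in place of the floor that median was -0.21. The tubular injury list had a median of -0.30 with 3 of 21 lower, Krt19 by 2.85-fold, and Lcn2 was lower by at least 1.56-fold. Heat shock and unfolded protein genes had a median of -0.20, with Hspa1a 2.74-fold and Hspb1 2.17-fold lower and the asparagine synthetase Asns 2.91-fold higher. All of these medians lay below all random lists, and the p53 list, with a median of -0.28, lay at percentile 0.010. The same array was low in fat and urothelial RNA: the adipose list had a median of -1.35, with Fabp4 3.57-fold lower but with log2 ratios of -1.63 and 0.21 on its other probe sets, and the urothelium list a median of -1.13, with Upk3b at least 3.57-fold, Psca 3.49-fold, Upk3a 3.10-fold and Upk1b 2.87-fold lower. Over genes detected in both arrays the adipose median was -0.46, and with a pseudocount the urothelium median was -0.42.

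Proximal tubule genes were close between the sham arrays. The proximal tubule list had a median of 0.01 with 0 of 38 members at 2-fold, Slc34a1 was 1.09-fold and Lrp2 1.06-fold higher, and the loop of Henle and distal tubule list had 0 of 17 members at 2-fold, although its median of -0.11 lay at percentile 0.020. The collecting duct list had a median of -0.06 at percentile 1.33, with Gata3 2.04-fold and Elf5 4.90-fold lower. Podocyte, endothelium and fibroblast lists had medians of 0.01, 0.14 and 0.02. Members of the fibroblast list went both ways, with quartiles of -0.60 and 0.35. Under quantile normalization the podocyte median was -0.0092. Fatty acid oxidation had a median of 0.13 at percentile 99.93, with Pdk4 2.63-fold lower. Complement and coagulation had a median of 0.15 at percentile 98.0, with Fgg 3.93-fold and Fga 2.10-fold lower. Cell cycle genes had a median of 0.18 and oxidative stress defence 0.12, both at percentile 99.8. The interferon response list had a median of 0.15 at percentile 99.3, and between the ischemia-reperfusion arrays 0.34 at percentile 99.8. The DNA methylation machinery had a median of 0.06, with Gadd45g 2.06-fold lower and Apobec2 2.32-fold lower on one of its probe sets and 0.05 in log2 ratio on the other. The cytokine list had a median of 0.05 and the apoptosis list a median of 0.03, each with 0 members at 2-fold.

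The comparison of the ischemia-reperfusion arrays asks how injured kidneys of the genotypes differed. Hp was 58.5-fold higher in the knockout-labelled array, Fabp4 16.97-fold, Sprr2f 16.7-fold, Akap12 13.3-fold, the neuropeptide gene Grp 11.3-fold, Ctla2a 9.78-fold and the acute phase gene Saa3 9.05-fold. Podxl was 11.5-fold higher on one probe set, with a log2 ratio of 0.29 on the other. The bounds were at least 49.9-fold for Cyp27b1, 12.0-fold for Adipoq, 11.8-fold for Calcb and 11.7-fold for AI506816. Lower were Cyp7b1 by 22.9-fold, Apoa4 by 16.6-fold, Slc22a19 by 14.1-fold, the tyrosine catabolism enzyme Hpd by 12.5-fold, Akr1c21 by 12.3-fold, the chemokine Cxcl12 by 10.9-fold and Slc22a7 by 10.7-fold. Ccl28 was 15.995-fold lower, with a log2 ratio of -1.70 on its other probe set, and the bounds among lower genes were at least 7.50-fold for Methig1, 7.41-fold for Slc4a1, 5.57-fold for Gm6958 and 4.86-fold for Slc7a12.

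Between the ischemia-reperfusion arrays 497 of 13492 measured genes were higher and 539 lower at 2-fold or more. The tubular injury list had 14 of 23 members higher, with a median log2 ratio of 1.19; the transcription factor Sox9 was 4.60-fold higher, Lcn2 2.90-fold and Havcr1 1.36-fold. Vcam1 was 4.59-fold higher, with other probe sets at log2 ratios of 0.26 and 1.51. The loop of Henle and distal tubule list had 13 of 17 lower, with a median of -1.31, Egf by 9.22-fold, Pvalb by 6.65-fold and Tmem52b by 4.57-fold. The proximal tubule list had 17 of 38 lower, with a median of -0.85; Slc7a13 was 6.98-fold lower, Hao2 5.69-fold, the water channel Aqp1 5.18-fold, Slc34a1 1.18-fold and Lrp2 2.48-fold, the last with log2 ratios of -1.11 and -0.11 on its other probe sets. Fatty acid oxidation had a median of -0.55 at percentile 0.095, with Cyp4a14 3.52-fold, Acadm 2.31-fold and Ehhadh 2.30-fold lower and Pdk4 4.26-fold higher. Complement and coagulation had a median of 0.63, or 0.31 with a pseudocount in place of the floor, with 5 of 16 higher, Fgb by 7.28-fold, the thrombin receptor F2r by 4.58-fold and Thbd by 4.196-fold, and immediate early genes a median of 0.62 with 8 of 21 higher, Dusp1 by 3.36-fold.

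Glomerular, vascular and stromal genes were higher in the knockout-labelled ischemia-reperfusion array, and so was fat RNA. The podocyte list had a median of 1.31 with 8 of 13 higher, Cdkn1c by 8.31-fold, Synpo by 6.65-fold and Ptpro by 5.61-fold, and the endothelium list a median of 0.96 with 7 of 15 higher, Emcn by 3.82-fold, Nos3 by 3.06-fold and Cdh5 by 2.77-fold. The fibroblast list had a median of 0.84 with 9 of 19 higher, Tagln by 5.89-fold, Tnc by 5.49-fold and Acta2 by 4.94-fold. Medians of these lists lay above all random lists, but with the median over each gene's probe sets they were 0.64 for podocyte and 0.31 for fibroblast genes. Nphs1, named after its values were seen, had log2 signals of 6.36 in the wild-type and 6.75 in the knockout-labelled array. The adipose list had a median of 1.10 with 4 of 7 higher, or a median of 0.025 over genes detected in both arrays, and the urothelium list a median of 0.14. Neutrophil genes had a median of 0.37, or 0.11 with a pseudocount, with S100a8 8.47-fold and S100a9 6.42-fold higher, and the cytokine list a median of 0.24, or 0.098 with a pseudocount, with 3 of 27 higher and 1 lower, Cxcl2 by 4.40-fold higher and Cxcl10 by 2.05-fold lower. The apoptosis list had a median of 0.18 with 3 of 28 higher, Mlkl by 3.70-fold and Bak1 by 3.23-fold, and Cdkn1a was 3.65-fold higher, whereas cell cycle genes had a median of -0.03 with 0 of 18 at 2-fold.

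**Figure D4:**
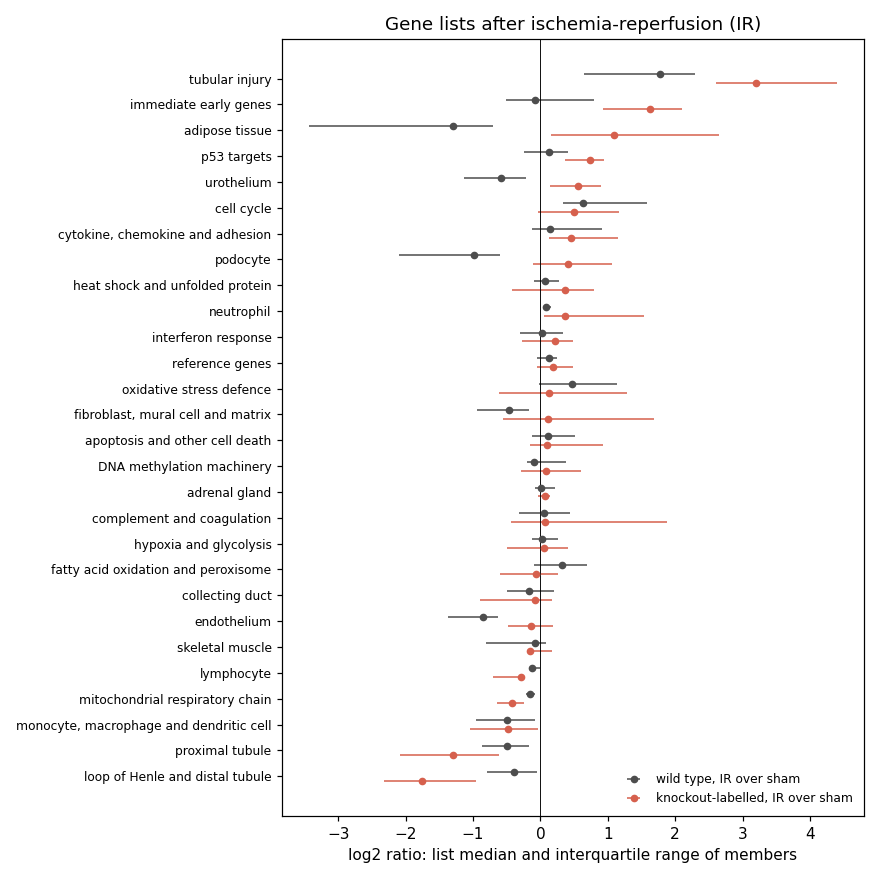
Median log2 ratio of ischemia-reperfusion to sham for 28 of the gene lists in both genotypes, points for medians and bars for the interquartile range of the members. The tubular injury list lies highest in wild type at 1.77 and in the knockout-labelled pair at 3.21, and the podocyte, adipose and urothelium lists lie below 0 in wild type and above 0 in the knockout-labelled pair.

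The difference of the responses asks whether ischemia-reperfusion acted differently in the genotypes. Across 13808 genes the responses correlated with Pearson r = 0.55 and Spearman rho = 0.49. Of the genes at 2-fold in wild type that were measured in both pairs, 479 of 564 went the same way in the knockout-labelled pair, and their median log2 ratio in that direction was 1.34 in wild type and 1.32 in the other pair. The 1741 genes at 2-fold in the knockout-labelled pair had a median of 1.42 there and 0.48 in wild type, with 1500 going the same way. At 2-fold, 202 genes were higher in both pairs against 16.8 for independent lists and 143 were lower in both against 20.1.

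The ratio of the knockout-labelled response to the wild-type response was 2-fold or more above 1 for 656 genes and below 1 for 658. Among genes over the floor in all 4 arrays, Hp led with a ratio of 219-fold, followed by Fabp4 at 60.6-fold, Car3 at 22.7-fold, though with a log2 value of 2.15 on its other probe set, Akap12 at 22.1-fold, Ifi27l2a at 20.3-fold, Nupr1 at 19.6-fold, the tight junction gene Cldn4 at 18.4-fold and Tnc at 15.3-fold. In the other direction stood Cyp7b1 at 23.0-fold, Slc22a19 at 21.0-fold, Apoa4 at 18.6-fold, Ccl28 at 13.5-fold with -2.09 in log2 on its other probe set, the peroxisomal oxidase Acox2 at 12.6-fold, Apoc3 at 12.1-fold, Mep1b at 11.7-fold and Serpina1f at 11.5-fold. Adipoq, at the floor in 2 arrays, had a ratio of at least 252.6-fold. Havcr1 had a ratio of 7.80-fold, with a log2 value of 1.87 on its other probe set. In the knockout-labelled arrays it was 5.72-fold lower after sham and 1.36-fold higher after ischemia-reperfusion than in wild type. Lcn2, at the floor in 1 array, had a ratio of at least 4.52-fold. The tubular injury list had 20 of 23 members at 2-fold or more, with a median log2 difference of 1.60, and immediate early genes 16 of 21 with a median of 1.49, led by Dusp1 at 7.08-fold, Egr1 at 6.45-fold and Junb at 5.30-fold. With the sham arrays exchanged between the genotypes, a control added after the data had been seen, the immediate early medians were 0.90 in wild type and 0.78 in the knockout-labelled array, in place of -0.09 and 1.62, and the tubular injury medians were 2.11 and 2.89, in place of 1.77 and 3.21. The proximal tubule list had a median of -0.80 and the loop of Henle and distal tubule list of -1.14, cytokine genes 0.15 and apoptosis genes 0.14. Podocyte genes had a median of 1.08, endothelial genes 0.95 with Emcn at 6.44-fold, and fibroblast genes 0.71 with Tagln at 8.88-fold, Acta2 at 8.80-fold and Postn at 8.25-fold; beside them the adipose median was 2.52 and the urothelium median 1.36. Under the alternatives the least of these medians were 0.64 for podocyte and 0.24 for fibroblast genes with the median over each gene's probe sets, 0.48 for adipose genes detected in every array, and 0.62 for urothelium genes with a floor at the 60th percentile.

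The genotype differences after sham and after ischemia-reperfusion did not track each other across genes, with Pearson r = -0.01 and Spearman rho = -0.01 over 13808 genes. Higher at 2-fold in both knockout-labelled arrays were 9 genes, against 0.77 for independent lists, among them Abhd1, at 17.8-fold after sham and 4.35-fold after ischemia-reperfusion, Azgp1 at 14.5-fold and 4.71-fold, Col5a2 at 7.99-fold and 3.90-fold, and Tmem87a at 3.80-fold and 8.34-fold. Lower in both were 16 genes against 4.33. A further 20 genes, against 3.71 for independent lists, were lower after sham and higher after ischemia-reperfusion, among them Adipoq, Fabp4, Hp and Nupr1.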

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

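The tests in this part were chosen after the results they bear on were seen, except 2 for the larger response: the scaling test was fixed before the data were examined, and exchanging the sham arrays was added after the data had been seen but before its own counts were. Differences between the genotypes below were not tested against a spread between mice, since each group had 1 pool.

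Ischemia-reperfusion moved 23 genes at 2-fold or more in opposite directions in the genotypes, which is why they were singled out; 18 were lower in wild type and higher in the knockout-labelled pair, and 5 the reverse, near the 17.4 and below the 19.4 that independent lists would share. The responses correlated across genes, with r = 0.55, so independent lists are a poor yardstick here and the nearness of these numbers decides nothing. Hp was 3.03-fold lower and 72.4-fold higher, Fabp4 9.65-fold lower and 6.28-fold higher, and Nupr1 4.48-fold lower and 4.37-fold higher. Because their list medians had opposite signs in the genotypes and lay outside the central 95% of random lists in both, podocyte genes were also singled out, with medians 1.39 apart on the log2 scale, and so were adipose genes, 2.39 apart, and urothelium genes, 1.16 apart; these differences were not tested. In the knockout-labelled pair the podocyte median was 0.12 with the median over each gene's probe sets, the adipose median 0.16 over genes detected in both arrays and the urothelium median 0.24 with a pseudocount, all within the upper limits of 0.32, 0.39 and 0.35 that random lists had as reported, so the opposite signs are weak there. Outside the gene comparisons, 60 of the 10092 probe sets without a single gene symbol were at 2-fold or more in the same direction after ischemia-reperfusion in both genotypes, 38 higher and 22 lower.

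The first pattern is the larger ischemia-reperfusion response of the knockout-labelled arrays, 1761 genes at 2-fold against 574. The values argue against unequal scaling left in the deposited columns, which at matching ranks lay within 0.10 of their mean and gave a ratio of the counts of 3.09 after quantile normalization, a step that could move little for that reason; the authors' own scaling stays open. They also argue against a difference between the sham arrays, since the ratio was 3.08 with the wild-type sham array as control for both. This holds for the counts. With that control immediate early genes kept a gap, with medians of -0.09 in wild type and 0.78 in the knockout-labelled array. The p53 medians were 0.13 and 0.25 in the same order. Heat shock medians were 0.06 and -0.07, so for that list the larger response ended. Fat and urothelial RNA may add single genes such as Adipoq. Against the wild-type sham array the excess of counts stayed, while the adipose list had a median log2 ratio of -0.66. Of its 8 members 1 was higher and 3 were lower. Adipoq had log2 signals of 9.31 against 10.11 in wild-type sham, but Fabp4 had 13.04 against 12.22. Fat RNA was thus not higher as a whole there, although some of its genes still were. The genotype and a more severe ischemia in that pool of mice also remain, and neither was tested, because each group had 1 pool. The technical SD was 0.41 in the knockout-labelled pair and 0.24 in the wild-type pair. How far technical error added to the counts was not tested.

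The second pattern is the lower signal of podocyte, endothelial and stromal genes in the wild-type ischemia-reperfusion array. Less fat and renal pelvis in the RNA is an unlikely sole cause for the podocyte genes, since the knockout-labelled sham array, low in both, had a podocyte median log2 ratio of 0.014 against wild-type sham. A smaller share of podocytes in that RNA cannot be told apart from lower expression: of the podocyte list members well over the floor, chosen for this test after their values were seen, the least lower was Ildr2 with a log2 ratio of -0.24, while Tcf21 had -2.71, Podxl -2.44 and Ptpro -2.33. Mme and Enpep, with -0.71 and -0.27, are also made by tubule cells, which keeps that explanation open. Injury of glomeruli and vessels by ischemia in wild type was not tested separately.

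The third pattern is the Tet2 signal of the knockout-labelled arrays together with the genes that differed from wild type after both treatments. A stock of mice shared by both labels, or labels exchanged in 1 pair, cannot be told apart. Taken alone, the genes higher after sham argue against it, with 9 higher in both knockout-labelled arrays. Of them 0 were lower after ischemia-reperfusion. Among genes lower after sham 16 were lower in both and 20 opposite. Independent lists would share 3.71 of the opposite kind, so such lists are a poor yardstick with 1 pool per group. DNA of another strain kept around Tet2 could account for none of the 9 higher genes through neighbours, with 0 on the chromosome that carries Tet2. For the 16 lower genes it cannot be told apart, since 5 lie on that chromosome against 0.77 by chance. Named after their values were seen, these are Acad9, D3Ertd751e, Mttp, Slc7a12 and Sprr1a. Of these, Mttp alone is among the 200 measured genes nearest to Tet2, at a distance of 16 measured genes. Its log2 ratio to wild type was -1.71 after sham and -2.09 after ischemia-reperfusion. The upper limit of random draws was also 1 gene among those 200. Other genes, also named after their values were seen, may make the excess on the chromosome less particular. Car3, Fabp4, Fgg and Sptssb lie on the same chromosome. Unlike the 5, they were lower after sham and higher after ischemia-reperfusion. Apobec2, Apom, BC040756 and Sult1c2, among the 16 lower genes, lie together on chromosome 17. Probe sets outside the deleted part of Tet2 also stay open, since the highest log2 ratio between the sham arrays was 0.41 and no genome with the probes and the deletion was used here.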

How the results depend on the processing

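The use of the other genotype's sham array as control was added after the data had been seen, though before its own counts were; the other alternatives were fixed before the data were examined. Under the alternatives 92 counts stayed within 1.5 times the reported one and 22 did not. For the 4 main lists 152 medians moved by less than the technical SD and 8 by more. For other lists 924 moved by less and 40 by more. That SD belongs to single genes and is wide for a list median, so a small median could vanish without passing it. Apart from the exchange of the sham arrays, no list median beyond its random range turned its sign. With it the urothelium median in wild type turned from -0.59 to 0.38 and the collecting duct median from -0.17 to 0.08. In the knockout-labelled array the heat shock median turned from 0.37 to -0.07. The adipose median there turned from 1.10 to -0.66 and the urothelium median from 0.56 to -0.46. The ratio of the response counts, knockout-labelled over wild type, ranged from 2.39 to 3.63. With the other genotype's sham array as control 273 genes were higher and 316 lower in the wild-type ischemia-reperfusion array, and 867 and 899 in the knockout-labelled one. Quantile normalization kept 550 of 574 genes at 2-fold in the same direction in wild type and 1684 of 1761 in the knockout-labelled pair.

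By construction, a threshold of 1.5-fold gave more genes: 809 higher and 851 lower in wild type after ischemia-reperfusion, 1985 and 1977 in the knockout-labelled pair, 138 and 327 between the sham arrays, 1424 and 1416 between the ischemia-reperfusion arrays, and 1534 and 1721 for the difference of responses. By construction too, 3-fold gave fewer, in the same order 91 and 103, 307 and 398, 10 and 38, 152 and 184, and 227 and 212. A floor at the 60th percentile gave 16 genes higher between the sham arrays, r = 0.58 between the responses, a tubular injury median of 1.48 in wild type, and cytokine medians of 0.58 in wild type and 0.96 in the knockout-labelled pair. A floor at the 20th percentile gave r = 0.53. The pseudocount gave 196 genes lower in wild type, r = 0.57, cytokine medians of 0.031 in wild type, 0.13 in the knockout-labelled pair and 0.098 between the ischemia-reperfusion arrays, apoptosis medians of 0.059, 0.024 and 0.070 in the same order, and tubular injury medians of 1.48 in wild type and 2.79 in the knockout-labelled pair. Detection in every array compared gave r = 0.57 between the responses, r = 0.0034 between the genotype differences and a tubular injury median of 1.51 in wild type. The median over a gene's probe sets gave tubular injury medians of 1.44 in wild type and 1.21 for the difference of responses, and plain _at probe sets gave r = 0.54. Apart from the thresholds, the cause was not tested.

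The threshold of 3 robust SDs removed no gene and so says nothing about stability. No paired analysis was possible because within each comparison there was 1 array on either side, and leaving out an array or permuting labels was impossible for the same reason. An additive fit of treatment and genotype over the 4 arrays, which takes the difference between the responses for error, was not run. Signals near the floor limit what can be said of weakly expressed genes such as Il6, Ccl2 and Tet1, and folds against the floor are lower bounds.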

Other observations

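Leukocyte genes went both ways after ischemia-reperfusion. The monocyte, macrophage and dendritic cell list had a median log2 ratio of -0.49 in both pairs, below all 10000 random lists. In wild type Cd68 was at least 4.94-fold and Cd14 2.83-fold higher, while the complement gene C1qa was 3.09-fold and the lysozyme gene Lyz2 2.996-fold lower. In the knockout-labelled pair Cd14 was 20.5-fold, Chil3 at least 8.56-fold and Cd68 at least 4.46-fold higher, and the growth factor receptor gene Csf1r was 4.82-fold lower. Between the ischemia-reperfusion arrays this list had a median of 0.02, which ranged from -0.15 to 0.21 under the alternatives and was -0.0020 under quantile normalization. Neutrophil genes in wild type had a median of 0.08, with S100a8 at least 2.34-fold and S100a9 1.98-fold higher. The lymphocyte list had medians of -0.13 in wild type and -0.29 in the knockout-labelled pair, with the antibody joining chain gene Jchain lower by at least 4.25-fold and at least 4.47-fold. Interferon response genes had a median of 0.02 in wild type, which turned to -0.0031 with a common median and -0.14 with plain _at probe sets alone, and 0.21 in the knockout-labelled pair at percentile 96.0, or 0.020 with plain _at probe sets; Gbp3 was 2.55-fold higher in wild type, and Ifi35 2.15-fold on the highest of its probe sets, Gbp2 2.06-fold and Ifit2 2.01-fold higher in the knockout-labelled pair.

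The hypoxia and glycolysis list had medians of 0.03 and 0.05, the latter -0.01 with a common median, with the vasodilator gene Adm 2.34-fold higher in wild type and 2.45-fold in the knockout-labelled pair, where Hk2 was 2.95-fold higher and Car9 2.57-fold and Pdk1 3.05-fold lower, with log2 ratios of -0.73 and -0.22 on the other probe sets of Pdk1. Mitochondrial respiratory chain genes had medians of -0.15 and -0.42, at percentiles 4.35 and 11.0, and Ndufs1 was 2.496-fold lower in the knockout-labelled pair. The heat shock and unfolded protein list had a median of 0.06 in wild type, with Hspb1 2.87-fold and Asns 2.63-fold higher. DNA methylation machinery had medians of -0.10 and 0.08; Uhrf1, which guides maintenance methylation, was higher by at least 3.44-fold and at least 3.22-fold, and the methyltransferase Dnmt1 was 2.26-fold higher in the knockout-labelled pair, where Tet2 was 3.14-fold and 2.19-fold lower on its probe sets. In wild type Tet2 was 1.45-fold and 1.74-fold lower. The adrenal list had medians of 0.01 and 0.07, the former -0.01 with a common median, with 0 of 6 members at 2-fold, the skeletal muscle list -0.08 and -0.16, and the red blood cell list, with 3 members measured, -0.44 in wild type. Reference genes had medians of 0.13 and 0.19, with 0 of 12 at 2-fold in either pair.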
